A study of Mus musculus with 4 samples.

How the data were processed

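Bulk RNA-seq libraries of sorted mouse DP thymocytes were compared between control and Cxxc1 KO mice, with 2 libraries per genotype. Total RNA was extracted with TRIzol, and libraries were built from 10 ng of RNA with an integrity number above 8 by a SMART-seq Standard kit, per the labels' protocols. Such kits amplify cDNA by PCR, and no molecular identifiers were used here, so counts are reads rather than molecules. The deposited files hold whole-number counts per gene symbol for 35976 symbols, 1 file per library, not normalised. The files' headers name a HISAT2 alignment, and the submitters' processing notes name cutadapt 4.0, HISAT2 2.2.1, featureCounts 2.0.8, edgeR 3.36.0 and the mm10 genome, with no role or order. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Such reads affect families of near-identical genes, and unstranded counting mixes overlapping genes.

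Groups came from the sample titles, and no batch is given in the labels. Total counts were 12150508 in control 1, 34820446 in control 2, 36243182 in KO 1 and 33544428 in KO 2. A floor of 3 counts corresponded to 0.247, 0.0862, 0.0828 and 0.0894 CPM in these libraries, and such floors cover counting error only. Every pair of libraries differed by far more than counting error (chi-square per degree of freedom of at least 57.3), so none was treated as a duplicate. Libraries made from the same RNA could also exceed counting error, so this value cannot show that they came from separate samples. Abundant small noncoding RNAs (Rpph1, Rn7s1, Rn7s2, Rn7sk, Rmrp and LOC101056014) took 8.83%, 5.78%, 8.68% and 7.91% of counts. Ribosomal protein genes took 1.72%, 1.37%, 2.95% and 2.42%.

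Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15), which left 20389 genes, and libraries were scaled by TMM, with factors of 0.981, 0.997, 0.962 and 1.06. A quasi-likelihood model (estimateDisp, glmQLFit, glmQLFTest with package defaults) with genotype as the only term gave two-sided p-values, adjusted by Benjamini and Hochberg's method, and a gene was called at an adjusted p below 0.05. The biological coefficient of variation was 57.4%, with 2 residual degrees of freedom and a median total of 9.19 after moderation. The standard error of a log2 fold change was its size divided by the square root of the F statistic, and its median was 0.29 for genes above 10 CPM. CPM values use TMM-scaled library sizes. DESeq2 1.42.0 was an alternative, in which 396 genes had no adjusted p. Coordinates are RefSeq gene spans on GRCm38.p6, the assembly that mm10 names, and 32501 of the 35976 symbols had a match.

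Before the data were examined, the main test and its alternatives, 36 gene lists in 3 families (T-lineage, cell state, and technical or other cells) and the naming rule were fixed. Lists with at least 3 tested members, 33 of them, were tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 33. camera compares a list with the other genes. The planned patterns for T cell receptor gene segments matched no symbols, so the Traj, Trav and Trbv lists gave no result. The planned pattern for mitochondrial genes also matched none, and the symbols of the 13 mitochondrial protein-coding genes as the files write them were used in its place after the files were seen. camera called 13 lists, 5 up and 8 down. With a correlation estimated for each list it called 0 and fry called 0, with 1 and 4 lists at an unadjusted p below 0.05. fry tests whether a list's genes move one way on balance, and does not compare the list with other genes.

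The naming rule took 14 preset genes whatever their values, and the 10 higher and 10 lower called genes with the largest fold change, at least 10 CPM in the higher genotype and libraries that did not overlap, without predicted-gene and clone symbols (Gm followed by digits, LOC, ending in Rik, or containing -ps). Per list it took up to 3 called members with the smallest p, or the 2 members with the highest CPM as examples where none was called. Some genes that the rule names are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

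The tests were checked on simulated counts for this comparison, made from the means, library sizes and dispersions of the real libraries, with 20382 genes of which 200 were changed. The main test made 175 calls, of which 13.7% were false, above the nominal 5%. It recovered 28% of 2-fold changes, 74% of 4-fold changes and all 8-fold and 16-fold changes. The changed genes were all drawn from those with a mean of at least 5 CPM, and the counts were simulated once. Recovery in genes below 5 CPM was therefore not measured. False calls were 19.7% for the likelihood ratio test, 25.5% for DESeq2 and 6.38% for edgeR's newer quasi-likelihood setting, which recovered 6% of 2-fold and 60% of 4-fold changes. For lists, camera with the preset correlation called both planted 2-fold lists and 0 of 20 unchanged ones, and the estimated correlation and fry called neither planted list. The simulated genes varied independently, so this does not test the preset under correlation.

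The alternatives covered scaling by DESeq2 size factors or by library totals only, no filter on low counts or at least 5 CPM in 2 libraries, DESeq2, the likelihood ratio test, the older quasi-likelihood setting, a replicate block, and each library left out in turn. The older setting is the default of this edgeR version, so it gave the same 92 calls. Added after the data were seen were the newer quasi-likelihood setting, counts thinned to the smallest library, and the small noncoding RNAs left out. Transcript lengths came from GENCODE M21, as the longest transcript of each gene. Tests outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Double-negative thymocytes were not analysed here.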

Results

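Gene expression was measured by bulk RNA-seq in CD4 and CD8a double-positive (DP) thymocytes, the stage at which developing T cells carry both coreceptors. The cells were sorted from mouse thymus as positive for CD24, which marks immature thymocytes, and negative for surface TCRb. Cxxc1 encodes a CXXC zinc finger protein that binds unmethylated CpG DNA and belongs to the SETD1 complexes, which methylate histone H3 at lysine 4. Control mice had intact Cxxc1 with the Lck-cre transgene, and Cxxc1 knockout (KO) mice had floxed Cxxc1 with the same transgene, which is active in T-lineage cells. There were 2 libraries per genotype. Counts assigned to genes totalled 12150508 and 34820446 in control 1 and control 2, and 36243182 and 33544428 in KO 1 and KO 2. Double-negative thymocytes, which the design also covers, were not analysed here. Nothing in the labels says that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Levels are library-size-normalised counts (CPM), given as mean ± SD with n = 2 per genotype, and log2 fold changes are KO over control ± standard error.

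By correlation, replicates were closer to each other in the KO than in the control group. Across tested genes, Pearson's r of log2 CPM was 0.944 between the KO libraries and 0.890 between the control libraries, against 0.873 to 0.893 between genotypes. The SD of the log2 difference over genes above 5 CPM had the same order, at 0.560 for the KO pair and 0.657 for the control pair. The order was the opposite by chi-square per degree of freedom, at 100.6 for the KO pair and 57.3 for the control pair. That chi-square was taken on raw counts, where variation beyond counting error weighs more in deeper libraries, so it cannot rank the pairs. Control 1 had the fewest counts, and the effect of its depth on these values was not tested. Genes are not independent replicates, so these values describe the libraries only. The Y-linked transcripts Ddx3y and Uty were present in all 4 libraries, at 61.6 to 129.7 and 68.4 to 113 CPM.

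The first check of the genotype labels was Cxxc1 itself (chromosome 18, 74216212 to 74221493 on GRCm38). Its level was 111 and 53.5 CPM in control 1 and control 2, and 35.7 and 39.4 CPM in KO 1 and KO 2. Both KO libraries lay below both control libraries, with a log2 fold change of -1.12 ± 0.34. The difference did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.199). Gene-level counts keep reads from exons outside the deleted part, and the position of the floxed exons is not given in the sources used here, so the remaining KO signal does not measure remaining protein. Without control replicate 1 the log2 fold change was -0.51, and without control replicate 2 it was -1.56, where it passed the threshold.

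The main comparison asked how loss of Cxxc1 altered the DP transcriptome. The coreceptor genes Cd4 and Cd8a and the T cell receptor (TCR)-induced genes Cd5, Nr4a1 and Egr1 were lower in KO DP thymocytes, and the Notch-dependent genes Il2ra, Myc, Notch3 and Dtx1 were higher. Cd4 and Cd8a fell 4.26-fold and 4.17-fold, while the interleukin-2 receptor alpha chain gene Il2ra rose 15.8-fold and the interleukin-7 receptor gene Il7r rose 47.8-fold. Of 20389 genes tested, 92 changed, 55 higher and 37 lower in the KO. Every one of the 92 differed by at least 2-fold, with a smallest absolute log2 fold change of 1.39. Smaller changes could be missed, since the test recovered 28% of 2-fold changes planted in simulated genes of at least 5 CPM. The sizes of the 92 therefore do not show that smaller changes were absent. In all 92, both KO libraries lay beyond both control libraries, which held for 46.8% of all tested genes, and chance alone gives 33.3%. The changed genes comprised 72 protein-coding genes, 14 long noncoding RNAs, 2 of other types and 4 with no match in the RefSeq table. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, and 2830 genes had an unadjusted p below 0.05. DESeq2 called 947 genes, 441 higher and 506 lower, which included all 92. Without KO replicate 1 the count was 9, of which 8 were among the 92, and of the named genes Rab44, Il2ra and F13a1 were among them; without control replicate 1 or 2 it was 555 or 619. With library totals only as the scaling, 67.6% of calls were higher, against 59.8% in the main comparison, at a minimum of 5 CPM the share was 48.2%, and without KO replicate 2 it was 45.6%, with 52 of the 92 among 103 calls.

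**Figure D1:**
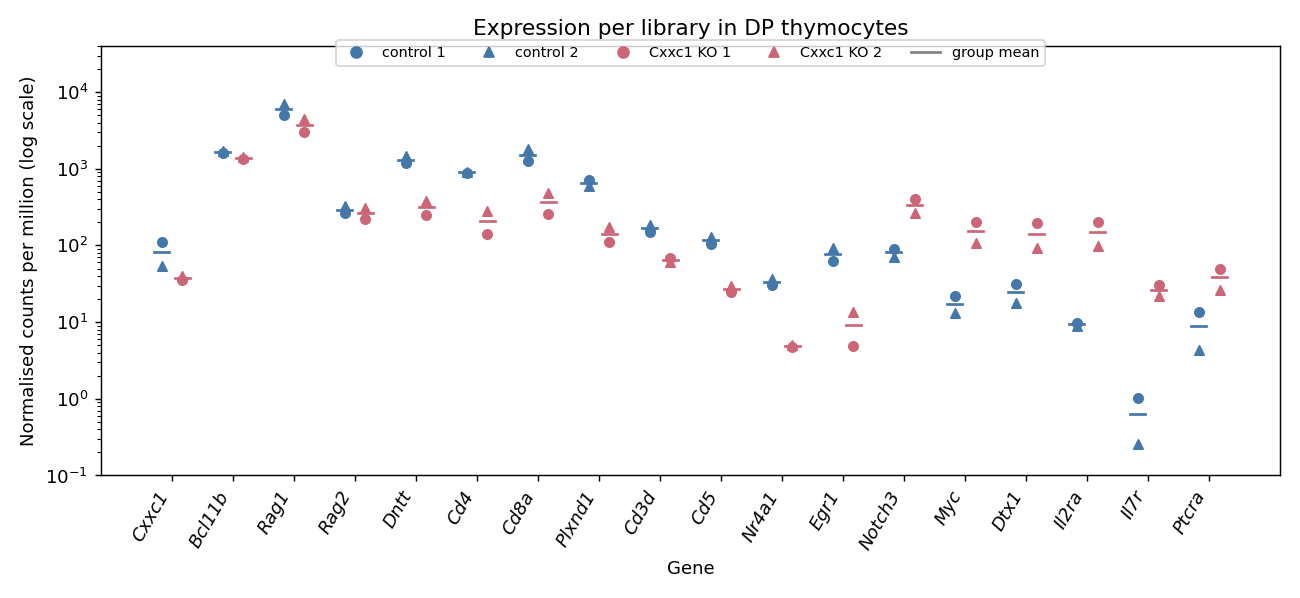
CPM (log axis) of 18 genes in each library, with circles for replicate 1, triangles for replicate 2 and bars for the mean of each genotype. Cd4, Cd8a, Dntt, Plxnd1, Cd3d, Cd5, Nr4a1 and Egr1 lie lower in both KO libraries (red) than in both controls (blue), and Notch3, Myc, Dtx1, Il2ra and Il7r lie higher.

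DP-stage genes were lower as a list, with 4 of 17 tested members falling and 13 not passing the test. Cd4 (chromosome 6, 124864693 to 124888247) fell from 895 ± 1.68 to 209.8 ± 95.5 CPM, a log2 fold change of -2.09 ± 0.32 (adjusted p = 0.0355). Cd8a (chromosome 6, 71373427 to 71379171) fell from 1534 ± 391 to 368 ± 155 CPM, by -2.06 ± 0.34 (adjusted p = 0.0442). Dntt (chromosome 19, 41029275 to 41059525), the terminal transferase that adds nucleotides at V(D)J junctions, went from 1320 ± 209 to 318 ± 95.2 CPM (-2.06 ± 0.28, adjusted p = 0.025). The semaphorin receptor gene Plxnd1 (chromosome 6, 115954811 to 115995339) went from 654 ± 70.1 to 142 ± 44.6 CPM (-2.21 ± 0.28, adjusted p = 0.0177). Cd8b1, the partner chain of Cd8a, had -1.60 ± 0.37 (adjusted p = 0.109). The recombinase genes Rag1 and Rag2 had -0.68 ± 0.30 and -0.13 ± 0.25, with adjusted p-values of 0.357 and 0.889. The chemokine receptor gene Ccr9, named after its values were seen, had -2.37 ± 0.43 (adjusted p = 0.06). Adjusted over the list alone, 8 members were lower and 0 higher. The list median was -0.68 (camera, adjusted p = 1.82e-11; adjusted p = 0.608 with an estimated correlation, the highest over 11 alternatives, whose lowest was 2.76e-19). The median was -0.41 without control replicate 2 and -0.38 without KO replicate 1, where the list remained called. Without KO replicate 1 the calls of Cd4, Cd8a, Dntt and Plxnd1 ended, at log2 fold changes of -1.65, -1.65, -1.74 and -1.88, and with library totals only those of Cd4 and Cd8a ended, at -2.04 and -2.01.

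Notch-dependent thymic genes were higher as a list, with 4 of 8 tested members rising, 0 falling and 4 not passing the test. Il2ra (chromosome 2, 11642792 to 11693194) rose from 9.43 ± 0.570 to 149 ± 73.3 CPM, a log2 fold change of 3.98 ± 0.37 (adjusted p = 0.00616). Myc (chromosome 15, 61985341 to 61990361), a growth-promoting transcription factor gene, rose from 17.4 ± 6.28 to 155 ± 64.8 CPM (3.16 ± 0.38, adjusted p = 0.0156). Notch3 (chromosome 17, 32120820 to 32166896) rose from 81.4 ± 13.7 to 335 ± 104 CPM (2.04 ± 0.28, adjusted p = 0.025). Dtx1, a Notch pathway ubiquitin ligase gene named after its values were seen, rose from 24.9 ± 9.80 to 143 ± 72.6 CPM (2.53 ± 0.41, adjusted p = 0.0408). Ptcra, which encodes the pre-TCR alpha chain, had 2.13 ± 0.55 (adjusted p = 0.138) and Notch1 had 1.71 ± 0.39 (adjusted p = 0.107). The Notch target Hes1 had 0 and 0.115 CPM in the controls and 16.9 and 3.03 CPM in the KO libraries (adjusted p = 0.0514). Nrarp, another Notch target, had -1.15 ± 0.67 (adjusted p = 0.497). Notch1, Hes1 and Nrarp were named after their values were seen. Adjusted over the list alone, 7 members were higher and 0 lower, and the list median was 2.33 (camera, adjusted p = 1.13e-18; adjusted p = 0.608 with an estimated correlation, the highest over 11 alternatives, whose lowest was 1.41e-31). Il2ra remained called without KO replicate 1, at 3.40, and the calls of Myc, Notch3 and Dtx1 ended at 2.69, 1.72 and 1.92.

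Genes of positive selection and TCR induction were lower as a list, with 3 of 15 tested members falling and 12 not passing the test. Cd5 (chromosome 19, 10718107 to 10739026), a surface regulator whose level follows TCR signal strength, fell from 118 ± 17.3 to 27.3 ± 3.20 CPM, a log2 fold change of -2.11 ± 0.25 (adjusted p = 0.0152). The TCR-induced nuclear receptor gene Nr4a1 (chromosome 15, 101253902 to 101274795) fell from 33.8 ± 4.61 to 4.87 ± 0.228 CPM (-2.79 ± 0.35, adjusted p = 0.0177). The immediate-early transcription factor gene Egr1 (chromosome 18, 34861207 to 34864956) fell from 77.3 ± 21.3 to 9.28 ± 6.19 CPM (-3.06 ± 0.47, adjusted p = 0.0355). The activation marker Cd69 and the EGR corepressor gene Nab2, named after their values were seen, had -2.69 ± 0.53 (adjusted p = 0.073) and -2.42 ± 0.42 (adjusted p = 0.0509). Adjusted over the list alone, 10 members were lower and 0 higher, and the list median was -1.81 (camera, adjusted p = 1.51e-15; adjusted p = 0.568 with an estimated correlation, the highest over 11 alternatives, whose lowest was 1.06e-15). Without KO replicate 1 the calls of Cd5, Nr4a1 and Egr1 ended, at -1.95, -2.71 and -2.47, and that of Egr1 also ended with library totals only, where the log2 fold change of Egr1 was -3.00.

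TCR signalling components were lower as a list, with 1 of 22 tested members falling and 21 not passing the test. The member that fell was Cd3d (chromosome 9, 44981769 to 44987052), which encodes the CD3 delta chain of the TCR complex, from 169 ± 25.3 to 64.6 ± 5.97 CPM (-1.39 ± 0.23, adjusted p = 0.0466). The proximal kinase gene Zap70 had 120.0 ± 0.455 and 69.0 ± 0.856 CPM, a log2 fold change of -0.80 ± 0.22 (adjusted p = 0.166). Rasgrp1, a Ras activator gene named after its values were seen, had -1.51 ± 0.26 (adjusted p = 0.0509). Adjusted over the list alone, 4 members were lower and 0 higher, and the list median was -0.35 (camera, adjusted p = 3.52e-05; adjusted p = 0.625 with an estimated correlation, the highest over 11 alternatives, whose lowest was 2.65e-06). The median was -0.56 without control replicate 1 and -0.20 without control replicate 2, where the list remained called. The call of Cd3d ended without KO replicate 1, without KO replicate 2 and with library totals only, at -1.45, -1.29 and -1.36.

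Chemokine receptor and homing genes were lower as a list, with 1 of 12 tested members falling, Plxnd1, which is also in the DP-stage list. The largest point falls, of Cd69 (-2.69 ± 0.53) and Ccr9 (-2.37 ± 0.43), were also of members of the positive selection and DP-stage lists. The list is therefore not separate from those lists. The list median was -1.05 (camera, adjusted p = 1.34e-05; adjusted p = 0.608 with an estimated correlation, the highest over 11 alternatives, whose lowest was 8.31e-07). Adjusted over the list alone, 6 members were lower and 1 was higher. The higher one was Itga4, the alpha 4 integrin gene, at 272 and 722 CPM (1.41 ± 0.25, adjusted p = 0.0518 over all genes), named after its values were seen.

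T-lineage transcription factors were lower as a list by a small amount, with 0 of 19 tested members called by edgeR, 3 lower at an unadjusted p below 0.05 and 3 lower by DESeq2. Bcl11b, the T-lineage commitment factor named in the study's title, had 1657 ± 74.6 and 1377 ± 68.0 CPM, a log2 fold change of -0.27 ± 0.23 (adjusted p = 0.679). Tcf7, which encodes TCF1, had -0.32 ± 0.23 (adjusted p = 0.621), and the chromatin organiser gene Satb1 had -1.11 ± 0.28 (adjusted p = 0.138). Runx3, a CD8-lineage factor gene, had 0.56 ± 0.41, and Zbtb7b, the CD4-lineage factor gene also called ThPOK, was near the detection limit at 0.462 ± 0.654 and 0.253 ± 0.277 CPM. Satb1 and Foxo1, the latter named after its values were seen, were among 3 members lower over the list alone. The list median was -0.27 (camera, adjusted p = 0.0337; adjusted p = 0.608 with an estimated correlation, the highest over 11 alternatives, whose lowest was 0.00373). The list lost its call without control replicate 1, without control replicate 2 and without KO replicate 2, at medians of -0.31, -0.22 and -0.32.

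Il7r (chromosome 15, 9506159 to 9529941) stood in both the early progenitor list and the mature single-positive list, since its expression is high before and after the DP stage. It rose from 0.634 ± 0.530 to 26.3 ± 6.12 CPM, a log2 fold change of 5.58 ± 0.65 (adjusted p = 0.0152), and was the one called member of each list. Neither list was called. The early progenitor list had a median of 0.02 over 10 tested members (camera, adjusted p = 0.482), with 1 member higher and 2 lower over the list alone. The mature single-positive list had a median of -0.16 but a mean of 0.69 over 13 tested members, and camera's direction was up (adjusted p = 0.214), with 3 members higher and 3 lower over the list alone. Gzma, a cytotoxic granule protease gene, was the one called member of 14 tested innate-like and NK-lineage genes, rising from 10.4 ± 1.37 to 42.3 ± 10.5 CPM (2.03 ± 0.33, adjusted p = 0.0442). That list had a median of -0.29 (camera, adjusted p = 0.965), and Id2, an inhibitor of E proteins, had 0.93 ± 0.86 (adjusted p = 0.708). The calls of Il7r and Gzma ended without KO replicate 1, at 5.29 and 2.30, and that of Gzma also without KO replicate 2, at 1.75, and with library totals only, at 2.08.

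The 15 subunits of H3K4 methyltransferase complexes, the family of complexes that Cxxc1 belongs to, did not move together. The list median was -0.10 (camera, adjusted p = 0.918), with 0 members called by edgeR, 2 higher at an unadjusted p below 0.05 and 0 called by DESeq2. Kmt2a had 0.15 ± 0.25 and Kmt2d had -0.38 ± 0.23.

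Among called genes with counts in both genotypes, predicted-gene and RIKEN clone symbols left out, the largest rises were those of Il7r and Rab44, a large Rab GTPase gene (chromosome 17, 29114128 to 29148980), which rose from 2.64 ± 0.758 to 127 ± 49.9 CPM (5.54 ± 0.40, adjusted p = 0.00144). Plac8 rose by a log2 fold change of 4.61 ± 0.67, Pgpep1l by 4.29 ± 0.45 and Unc93b1, which carries nucleic acid-sensing Toll-like receptors to endosomes, by 3.77 ± 0.50. The aryl hydrocarbon receptor gene Ahr had 3.25 ± 0.52 and Prr13 had 3.16 ± 0.44. With Il2ra, Myc and the globin gene Hba-a1, these made up the 10 largest rises under the naming rule. Adjusted p-values of Ahr, Pgpep1l, Plac8, Prr13 and Unc93b1 were 0.0403, 0.0105, 0.0272, 0.025 and 0.0212. Without KO replicate 1, Rab44 kept its call at 5.12, while Ahr, Pgpep1l, Plac8, Prr13 and Unc93b1 lost theirs at 2.84, 4.04, 4.37, 3.55 and 3.59. Without KO replicate 2, Ahr, Plac8 and Prr13 lost theirs at 3.60, 4.87 and 2.72.

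With the same symbols left out, the largest falls under the naming rule were those of Sdc4, a cell-surface proteoglycan gene, at -3.90 ± 0.55, Spsb1 at -3.74 ± 0.55 and Cd52, a lymphocyte surface glycoprotein gene, at -3.68 ± 0.46. The MAP kinase phosphatase gene Dusp4 followed at -3.14 ± 0.51, then Egr1, Map4k5 at -2.82 ± 0.48, Nr4a1, the junction protein gene Jup (plakoglobin) at -2.75 ± 0.43 and the adhesion molecule gene Ncam1 at -2.66 ± 0.39. F13a1, the coagulation factor XIII A chain gene (chromosome 13, 36867178 to 37050244), fell from 164 ± 8.45 to 27.1 ± 1.02 CPM (-2.59 ± 0.23, adjusted p = 0.00478). The adjusted p-values of Sdc4, Spsb1, Cd52, Dusp4, Map4k5, Jup and Ncam1 were 0.025, 0.0302, 0.0177, 0.0442, 0.0481, 0.0383 and 0.0299. RefSeq places other gene models over F13a1, Il2ra, Notch3, Rab44, Gzma, Map4k5, Ncam1 and Spsb1, and whether the counting used strand is not given in the sources used here, so their counts may hold reads of those models. F13a1 kept its call without KO replicate 1 at -2.52, and Sdc4, Spsb1, Cd52, Dusp4, Map4k5, Jup and Ncam1 lost theirs, at -4.34 (Sdc4), -3.54 (Cd52), -2.18 (Map4k5), -2.17 (Jup) and -2.83 (Ncam1), while the log2 fold change of Spsb1 was -3.50 and the log2 fold change of Dusp4 was -2.74. Without KO replicate 2, Sdc4, Spsb1, Dusp4 and Ncam1 lost theirs at -3.54, -3.98, -3.63 and -2.48, and with library totals only Dusp4, Jup and Map4k5 did at -3.08, -2.68 and -2.75.

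**Figure D2:**
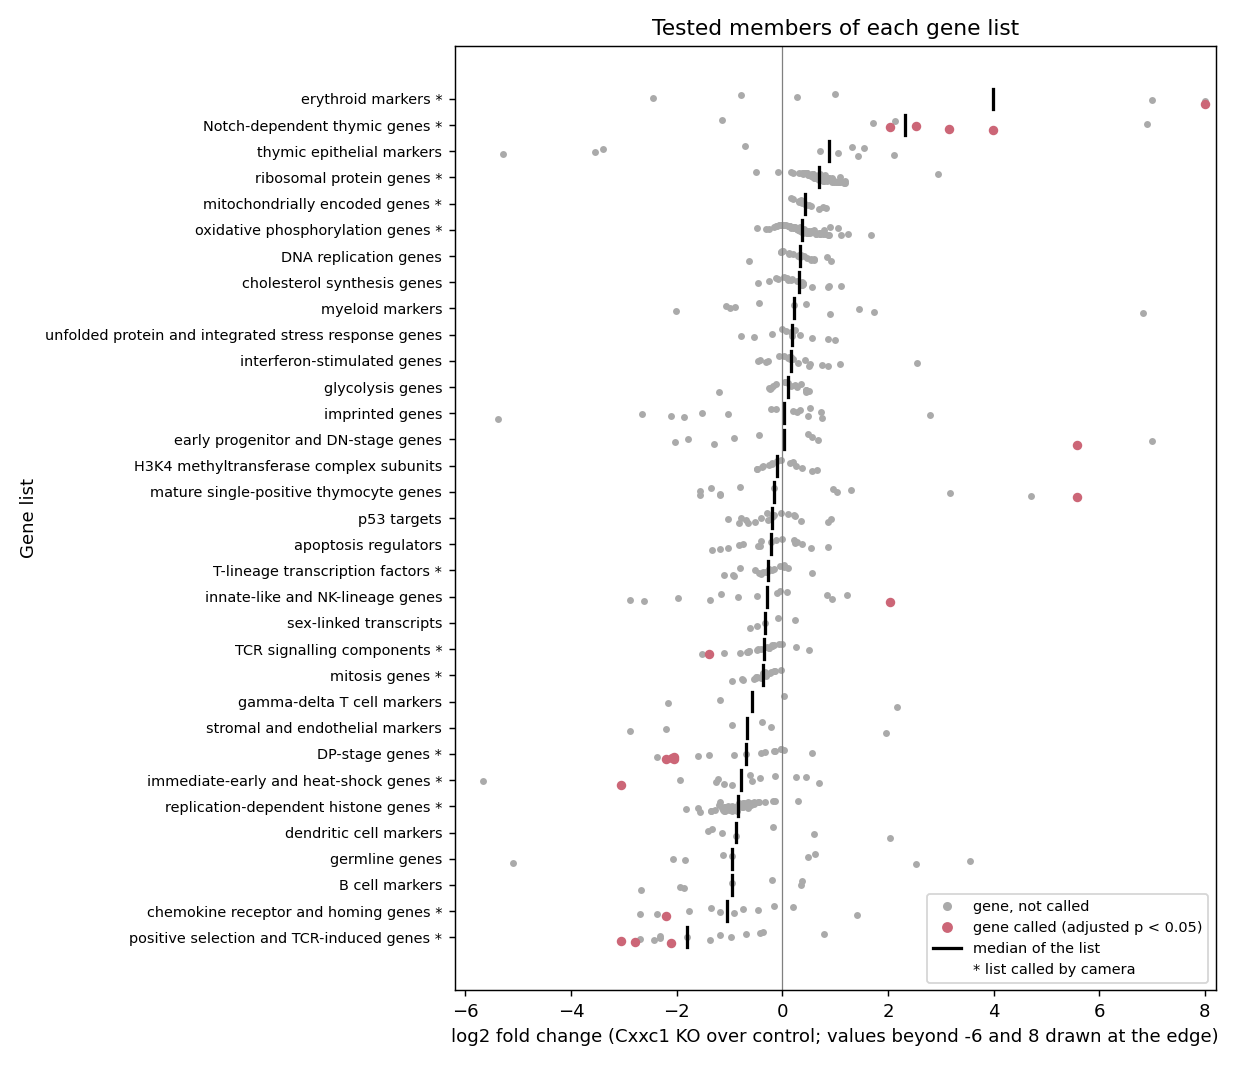
Log2 fold change (KO over control, horizontal axis) of the tested members of each of 33 gene lists, with red points for genes called, black bars for list medians and asterisks for lists called by camera. Lists run from a median of -1.81 for positive selection and TCR-induced genes at the bottom to erythroid markers at the top, whose bar rests on fitted folds of genes at 0 in the controls.

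Genes of translation and respiration were higher in the KO as lists. Of 81 tested ribosomal protein genes, 79 had higher point values, with a median of 0.70 (camera, adjusted p = 1.84e-25; adjusted p = 0.608 with an estimated correlation, the highest over 11 alternatives, whose lowest was 3.11e-35). edgeR called 0 of them over all genes and 40 higher over the list alone, with 51 higher at an unadjusted p below 0.05, and DESeq2 called 21 higher. Rplp0 had 996 ± 185 and 1882 ± 493 CPM (0.92 ± 0.28), and Rpl13a had 683 ± 126 and 1108 ± 404 CPM (0.70 ± 0.30). Nuclear oxidative phosphorylation genes had a median of 0.37 over 73 tested members (camera, adjusted p = 5.38e-06; adjusted p = 0.608 with an estimated correlation, the highest over 11 alternatives, whose lowest was 3.03e-07). edgeR called 0 of these, 12 were higher at an unadjusted p below 0.05 and DESeq2 called 1 higher. Sets of genes matched to these on expression and on the longest annotated transcript had medians of 0.195 on average. The central 95% of these medians ended at 0.299, so part of the 0.37 was shared by other genes of that annotated length and level. Atp5b had 0.39 ± 0.23 and Atp5a1 had 0.33 ± 0.22.

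The 13 mitochondrially encoded genes all had higher point values, with a median of 0.44 (camera, adjusted p = 0.00477; adjusted p = 0.827 with an estimated correlation, the highest over 11 alternatives, whose lowest was 8.67e-08). COX1 had 5437 ± 1151 and 7351 ± 2457 CPM, and ND5 had 1652 ± 181 and 2931 ± 1195 CPM. edgeR called 0 of them, with 2 higher at an unadjusted p below 0.05, and DESeq2 called 0. The mitochondrial share of counts was 1.19% and 1.61% in the controls and 2.36% and 1.53% in the KO libraries. The list lost its call without control replicate 1, at a median of 0.23, and without KO replicate 1, at 0.13, and remained called at 0.69 without control replicate 2 and at 0.67 without KO replicate 2.

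Both called cell-cycle lists were lower in the KO by group, though in neither did the median of control 2 lie above that of KO 1. Mitosis genes had lower point values in all 20 tested members, with a median of -0.36 (camera, adjusted p = 0.00192; adjusted p = 0.827 with an estimated correlation, the highest over 11 alternatives, whose lowest was 1.76e-06). Mki67, a proliferation marker, had -0.29 ± 0.26, and the topoisomerase gene Top2a had -0.49 ± 0.27. Replication-dependent histone genes had lower point values in 64 of 65 members, with a median of -0.85 (camera, adjusted p = 3.45e-14; adjusted p = 0.821 with an estimated correlation, the highest over 11 alternatives, whose lowest was 1.04e-44). edgeR called 0 of either list, with 3 mitosis and 23 histone genes lower at an unadjusted p below 0.05, and DESeq2 called 1 and 6 lower. The histone medians per library, centred on each gene's mean, were 0.958 and -0.129 in control 1 and control 2 and 0.079 and -0.893 in KO 1 and KO 2. In the same order, the mitosis medians were 0.412, -0.005, 0.005 and -0.364. Histone genes are near-identical copies, so their single-gene counts are uncertain. Their transcripts are mostly non-polyadenylated, and whether this affected their counts was not tested. The mitosis list lost its call without control replicate 1 and without KO replicate 2, at medians of -0.15 and -0.20, and had -0.59 without control replicate 2. The histone list lost its call without control replicate 1, at -0.22, and remained called at -1.29 without control replicate 2, at -1.36 without KO replicate 1 and at -0.46 without KO replicate 2. DNA replication genes had a median of 0.33 over 20 members and were not called (camera, adjusted p = 0.112); they were called without control replicate 1 and without KO replicate 2, at medians of 0.74 and 0.74. Mcm6, a replicative helicase gene, had 0.60 ± 0.30, and Uhrf1 had 0.12 ± 0.44. The DNA replication medians per library were 0.244 and -0.473 in control 1 and control 2 and 0.658 and -0.354 in KO 1 and KO 2.

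Immediate-early and heat-shock genes, which respond to handling as well as to signalling, were lower as a list. Egr1 was the one called member of 14 tested, 3 were lower over the list alone, and the median was -0.78 (camera, adjusted p = 0.00547; adjusted p = 0.608 with an estimated correlation, the highest over 11 alternatives, whose lowest was 0.000886). Without control replicate 1 the list lost its call, at a median of -0.39.

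Erythroid markers were higher in the KO as a list. The alpha globin gene Hba-a1 (chromosome 11, 32283672 to 32284486) had 0 counts in both controls and 14.6 and 6.49 CPM in the KO libraries, at least 163-fold higher against a floor of 3 counts over the control group. Hba-a2 and Hbb-bs, named after their values were seen, were also at 0 in the controls and at least 57.3-fold and 51.6-fold higher against the same floor. Hba-a1 was the one called member of 8 tested, and 3 were higher over the list alone. The list median was 2.03 with genes at 0 in a group set to their bound (camera, adjusted p = 0.000751; adjusted p = 0.608 with an estimated correlation, the highest over 10 alternatives, whose lowest was 0.00062). Hba-a1 and Hba-a2 are near-identical copies that counting could split. The list lost its call without control replicate 1 and without control replicate 2, at fitted medians of 7.03 and 3.81, and Hba-a1 lost its call without KO replicate 1, which left the 6.49 CPM of KO 2 against 0, and with edgeR's newer quasi-likelihood setting.

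No list of other cell types was called apart from the erythroid markers. Medians were -0.96 for B cell markers (7 tested; Blnk 0.38 ± 0.67 and Cd79b 0.36 ± 0.51) and 0.22 for myeloid markers (11 tested; Itgam 0.90 ± 0.37 and Cd68 0.22 ± 0.55). Dendritic cell markers had a median of -0.88 over 7 tested genes, against an upward direction in camera, with H2-Ab1 at 0.60 ± 0.57 and Zbtb46 at -0.18 ± 0.47. Thymic epithelial markers had a median of 0.88 but a mean of -0.48 over 10, with Ly75 at 1.43 ± 0.34 and Ccl25 at 0.72 ± 0.35. Gamma-delta T cell markers had a median of -0.58 over 4 tested genes, against an upward direction in camera, with Sox13 at 2.16 ± 1.55 and Blk at 0.03 ± 1.44. Stromal and endothelial markers had a median of -0.67 over 6, with Pdgfrb at 1.97 ± 0.51 and Pecam1 at -0.22 ± 0.24. The adjusted camera p-values of these 6 lists were 0.429, 0.405, 0.965, 0.302, 0.965 and 0.786. Sex-linked transcripts had a median of -0.33 (adjusted p = 0.414). With genes below 5 CPM left out, thymic epithelial markers were called, at a median of 1.16.

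The remaining 8 lists, of stress, survival, metabolic, germline and imprinted genes, did not pass the test. p53 targets had a median of -0.19 (adjusted p = 0.540, with Btg2 at -0.03 ± 0.27) and apoptosis regulators had -0.22 (adjusted p = 0.183). In the latter list the survival gene Bcl2l1, which encodes BCL-XL, had 307 ± 13.2 and 122 ± 22.5 CPM, a log2 fold change of -1.33 ± 0.23 (adjusted p = 0.0533), and Mcl1 had -0.22 ± 0.22. Interferon-stimulated genes had 0.16 (adjusted p = 0.300, with Psmb8 at 0.50 ± 0.22), glycolysis genes 0.11 (adjusted p = 0.786, with Pkm at -0.12 ± 0.26), and cholesterol synthesis genes 0.32 (adjusted p = 0.140, with Srebf2 at 0.10 ± 0.24). Unfolded protein and integrated stress response genes had 0.18 (adjusted p = 0.302, with Phgdh at 0.86 ± 0.29). Germline genes had a median of -0.95, against an upward direction in camera (adjusted p = 0.918, with Stra8 at 2.53 ± 0.86), and imprinted genes had a median of 0.03 but a mean of -0.55 (adjusted p = 0.911, with Kcnq1ot1 at 0.49 ± 0.22). Some of these lists were called in an alternative, at a median of -0.29 for apoptosis regulators with genes below 5 CPM left out, 0.56 for interferon-stimulated genes without KO replicate 1, and 0.35 for stress response genes without KO replicate 2. Cholesterol synthesis genes were called without control replicate 1 and without KO replicate 2, at 0.58 and 0.54.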

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

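The settings added after the data were seen were thinned counts, the newer quasi-likelihood setting and the small noncoding RNAs left out. No call of the main comparison changed sign in any alternative. Both KO libraries lay beyond both control libraries in all 92 calls, so refitting these same libraries could hardly reverse a sign. The unchanged signs are therefore no separate support for the calls. The 92 calls were all shared with DESeq2, the likelihood ratio test, the fits with no filter, with at least 5 CPM and with thinned counts, 71 with library totals only, 52 without KO replicate 2 and 8 without KO replicate 1. The direction of Cxxc1 was lower in all 15 alternatives, from -1.56 to -0.51, with adjusted p-values from 0.000661 to 0.67. Its KO libraries also both lay below both controls, so its sign was bound to the same libraries.

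Counts of changed genes were higher in other tests and under other filters. In the order genes changed, genes higher in KO, genes lower in KO and genes changed at least 2-fold, they were 920, 529, 391 and 819 with no filter, 228, 110, 118 and 228 at 5 CPM or more, 947, 441, 506 and 841 in DESeq2, and 997, 456, 541 and 938 in the likelihood ratio test. With thinned counts they were 145, 79, 66 and 145, on 16593 genes tested. Library totals only gave 71 calls, 23 of them lower. The newer quasi-likelihood setting gave 119, without Hba-a1. The cause of these shifts was not tested, except that fewer genes were tested at 5 CPM and with thinned counts. The Cxxc1 log2 fold change passed the threshold with no filter, at -1.09 (adjusted p = 0.00827), and in DESeq2, at -1.15 (adjusted p = 0.0337).

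The labels do not say whether equal replicate numbers mark a shared day or litter, so whether same-numbered libraries share a batch is unknown. Deviations of same-numbered libraries correlated at 0.269 over 11018 genes above 5 CPM. With a replicate block 1599 genes were called, 934 higher and 665 lower (genes changed at least 2-fold: 1067), and Cxxc1 had -1.04 (adjusted p = 0.000661). The block called the 13 lists plus DNA replication genes.

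Leaving out each library in turn gave 9 to 619 changed genes, 7 to 370 higher, 2 to 262 lower and 9 to 619 changed at least 2-fold, and 9 to 14 lists. These fits leave 1 library in a genotype, which is assumed to vary like the other genotype. The lowest counts came without KO replicate 1, where 32 of the 35 called named genes lost their calls and 3 kept them. Cxxc1 ranged from -1.56 to -0.51. With an estimated correlation or with fry 0 lists were called. For the called lists, estimates ran from -0.043 (T-lineage transcription factors) to 0.924 (replication-dependent histone genes), against the preset of 0.01. Notch-dependent genes had 0.799, DP-stage genes 0.681 and ribosomal protein genes 0.559. Where genes of a list vary together more than the preset allows, its camera p-value is too small. Both other tests also called neither planted list in the simulation. Their 0 therefore does not show that the lists were unchanged. Control 1 was the shallowest library, and its floor of 0.247 CPM limits what can be seen of low genes there.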

Other observations

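Several genes outside the fixed lists also rose in the KO, and were chosen after their values were seen. The cell-cycle kinase gene Cdk6 rose from 110.0 ± 6.42 to 507 ± 187 CPM (4.61-fold, edgeR adjusted p = 0.0212), and the semaphorin and VEGF coreceptor gene Nrp1 rose from 64.2 ± 19.3 to 310.0 ± 57.8 CPM (2.27 ± 0.28, adjusted p = 0.0177). The estrogen receptor gene Esr1 rose from 4.32 ± 0.0486 to 22.8 ± 1.85 CPM (2.40 ± 0.38), the teneurin gene Tenm1 from 29.0 ± 9.76 to 122 ± 8.72 CPM (2.06 ± 0.29) and the arrestin-domain gene Arrdc4 from 4.64 ± 2.05 to 34.4 ± 11.4 CPM (2.86 ± 0.44). The classical MHC class I gene H2-K1 rose from 14.8 to 64.8 CPM (2.13 ± 0.30, adjusted p = 0.025), and related class I genes could take or give reads to it. Without KO replicate 1 all 6 lost their calls, at log2 fold changes of 1.81, 2.10, 2.35, 2.03, 3.20 and 2.40 in the order given, and without KO replicate 2 Esr1, Arrdc4 and H2-K1 lost theirs, at 2.48, 2.48 and 1.86.

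KO 1 lay further from the controls than KO 2 in 65 of the 92 called genes, with median distances of 2.55 and 2.24 on the log2(CPM + 0.5) scale. The long noncoding RNA gene Gm35107, named after its values were seen, was at 0 in both controls. It was at least 335-fold higher in the KO against a floor of 3 counts over the control group.

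In the patterns below, the tests of dilution, of less mature cells, of neighbouring genes and of transcript length, the thinned counts and the small noncoding RNAs left out were chosen after the main results were seen.

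Cd4 and Cd8a were lower while Notch-dependent genes were higher. Dilution of DP cells by cells that lack all of the DP-stage transcripts would lower these genes alike. They scattered beyond their standard errors (Cochran's chi-square test, Q = 159.6 on 16 degrees of freedom, p = 1.00e-25, treating genes as independent), with Rag2 at -0.13 beside Cd4 at -2.09. Diluting cells that keep some of these transcripts would also give scatter, and Tcf12 of this list is also a listed T-lineage transcription factor. Dilution by such cells therefore stays open. The lower depth of control 1 would shrink the changes after thinning or without that library, but Cd4, Cd8a, Dntt, Plxnd1, Il2ra, Myc, Notch3 and Dtx1 kept at least 0.949 of their log2 fold change. Less mature thymocytes inside the sort may account for it, though the CD4 and CD8a gate should remove cells without both proteins: 76.5% of the RNA would have to come from cells without Cd4. With no earlier-stage profile measured in the same way, this cannot be told apart from a change of these genes within DP cells lacking Cxxc1.

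Called genes lay next to each other more often than expected. Within 100 kb there were 11 pairs, all moving in the same direction, against a mean of 1.25 and at most 8 in 10000 random draws matched on gene type and expression (permutation p = 0.0001, the smallest the draws can give). They include Pgpep1l with Gm16157 and Gm16158, Myo7a with Capn5, Cyth4 with Elfn2, and Nrp1 with Gm32643. Overlapping gene models counted on the same reads account for only 3 pairs, and the other 8, in 6 regions, were still more than nearly all draws held, with a mean of 1.11 and at most 8 (permutation p = 0.0002). A segment carried along with the floxed allele would gather calls near Cxxc1 on chromosome 18, and none of the pairs lay on that chromosome. Such a segment would therefore not hold these pairs. Within 10 Mb of Cxxc1, 1 of 120 tested genes was called (Poli), against 0.564 for random genes. These counts are too small to decide whether a segment was carried along. Transcripts running on past a gene's end, paralogs such as Gm4759 and Gm8995 and shared regulation in the KO may each explain pairs, and were not tested.

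Ribosomal protein genes were higher by a median of 0.70. To compare genes of similar length, 10000 sets were matched on expression and on the longest annotated transcript of each gene. Their medians were 0.134 on average, of which the central 95% ended at 0.258. The median longest transcript was 1094 bases for ribosomal protein genes and 1205 for matched genes. A longest transcript can exceed the expressed one, so this match cannot decide whether short transcripts account for the rise. Small noncoding RNAs taking counts do not account for the rise: without them the median was 0.703, and their share could shift all other genes by at most 0.0475. Variation between libraries stays open, since the medians per library, centred on each gene's mean, were -0.16 and -0.571 in the controls and 0.568 and 0.164 in the KO, and so does an untested effect of genotype.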
